A study of Mus musculus with 6 samples.

How the data were processed

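The 6 arrays are Agilent one-colour (Cy3) mouse gene expression arrays of the 8x60K format, hybridised with total RNA of spleen. Per the labels' protocols, RNA was taken from spleens of resting mice or of mice 24 h after total body irradiation, isolated with TRIzol from homogenised whole splenocytes and purified with RNeasy. Each array stands for a pool of 3 mice, and there were 3 arrays at 0 cGy and 3 at 900 cGy. Groups and replicate numbers came from the sample titles.

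Per the file headers and the submitters' processing notes, the images were read with Agilent Feature Extraction 10.5.1.1, which gave for each of 62976 spots the deposited intensity values used here, namely the mean spot intensity, the median intensity of the local background, and a processed intensity. Per the file headers, the processed intensity was background-subtracted and detrended within the array, with weak spots replaced by a surrogate value, and was not normalized between arrays. Because of that replacement, dim genes have compressed or unreliable folds, and such genes are given as bounds. The authors' deposited value table holds log2 values; set against the scanner values it was found to be scaled to the 75th percentile and centred on each probe's median over the 6 arrays (Pearson r over probes between 0.99995 and 0.99998 per array, slopes near 1.00), in the same direction. The medians of its columns were 0.047, -0.0059 and -0.046 for unirradiated replicates 1 to 3 and -0.025, 0.018 and -0.0083 for the irradiated ones. That table was used as an alternative.

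Each array's log2 processed intensity was reduced by the log2 of its 75th percentile over the 59305 non-control spots. The 75th percentiles were 1166, 1152 and 1403 for the unirradiated and 1144, 1114 and 1182 for the irradiated arrays. The 3671 control spots and between 91 and 146 spots per array that the scanner software marked as non-uniform or population outliers were left out, and spots of 1 probe were averaged. Of 55681 distinct probes, 27235 were named through their accession, 3581 through their symbol and 565 through a synonym in a RefSeq table of assembly GRCm38.p6, and 24300 kept the name in the files; none of that table's coordinates was used. Probe positions are those in the files, on mm9. Each gene was represented by the probe with the highest mean over the 6 arrays, and it was kept if that probe was well above background on all 3 arrays of at least 1 group, which left 26639 genes. Old symbols of list members were matched through a short alias table. Every probe of a gene named by the rule below that passed the background filter went in the same direction as the probe reported. The size of the change could differ between probes of a gene, as it did for Ermap and Flt1.

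Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Where a gene was not well above background on any array of a group, by any of its probes, the fold is a lower bound: the bright group's mean against the mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal. Such a bound holds for the main processing only. For each gene named with a bound, an alternative gave a change below it. For 30 gene lists with 574 entries, of which 569 had a probe and 560 were tested, members past the threshold were counted, and camera from limma with a preset correlation of 0.01 compared each list with all other genes, adjusted over the 30 lists; camera with an estimated correlation and fry were alternatives. With camera's preset correlation 20 lists passed, 12 higher and 8 lower; with an estimated correlation none did, the smallest adjusted p being 0.0605; and fry, which does not compare a list with other genes, called 25. Adjusted over the list alone, the counts of members were equal for 25 lists, and the report gives those of the other 5.

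The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took, among genes past the threshold with a symbol and outside multigene families, the 8 largest and 8 smallest log2 changes among genes well above background on all 6 arrays, the 3 largest bounds in each direction among genes that were not well above background in 1 group, and in each list the 3 members with the largest change. The families and clone names to be excluded were written down after the data were seen, and 1 of them, the kallikrein 1-related genes, was added after a member, Klk1b11, had come up by the rule; Cldn3 took its place. Members of a list named as its exceptions were chosen after their values were seen. So were the members of the BCL2 family and progenitor lists beyond their first 3, and Hba-a1, Hbb-b2, Ins1, Ins2, Xist and Ddx3y. Results of a few genes that the rule took are not reported here. The alternatives fixed beforehand were other background corrections, quantile normalization, scaling to the median gene or to spike-in probes, the deposited value table, other filters and probe summaries, an intensity trend with robust variances, a replicate block, a stricter threshold and leaving out each array. The changes of 9 pairs of lists were compared after the data were seen, by exact permutation of the 6 arrays, which cannot give a p under 0.1. List members were also tabulated under the spike-in and median scalings after the data were seen. Alternatives added after seeing the data were the pancreas list score of each array as a covariate, and the first row of the slide alone.

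All 6 arrays lay on 1 slide and were scanned together, so slide and scan could not separate the groups or serve as a block. The 3 unirradiated arrays and irradiated replicate 1 lay in row 1 of the slide, and irradiated replicates 2 and 3 in row 2. The SD of repeated spots of 1 probe within an array was 0.067 to 0.075 on the log2 scale, and the median SD of a gene between arrays was 0.17 in the unirradiated and 0.094 in the irradiated group. The closest pair, irradiated replicates 2 and 3, correlated at r = 0.998 across genes and differed by a median of 0.083; they were kept apart, since Ins1 differed between them (-1.57 and -3.91).

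The chain from spots to calls was tested on data simulated from the real means and spreads of the irradiated against unirradiated comparison, with 200 genes changed among 26638. At a log2 change of 1, 57% of the changed genes were recovered, and at 2, 90% were; 3.29% of all calls were false. In a second simulation 1 list was shifted by a log2 change of 1, and each of the 3 list tests called it and none of the others. Noise was drawn independently for each gene there, so the simulated lists lacked the correlation between members of the real ones. That correlation was estimated at 0.97 for the replication list and 0.94 for the mitosis list. The simulation therefore cannot tell which of the 3 list tests suits the real data.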

Results

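Messenger RNA of mouse spleen was measured on 6 one-colour microarrays, 3 from mice that had received 900 cGy of total body irradiation (X-rays to the whole animal) 24 h earlier and 3 from mice that had received 0 cGy. The mice were of B10.BALB-16.C2A, which the series title calls congenic, and RNA of 3 mice was pooled for each array. The comparison asks which transcripts of the spleen differ 24 h after 900 cGy. Of 55681 probes, between 39031 and 41261 were well above background on an array, and no spot was saturated. Values are log2 signals relative to the 75th percentile of the array, and the number of arrays limits the precision. The arrays of a group are separate pools according to the design text, and p-values measure the spread between pools, not between mice.

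After irradiation, marker genes of red cell precursors, B cells, T cells and dividing cells were lower. Target genes of p53, interferon-responsive genes and marker genes of macrophages, stroma, endothelium, fat and exocrine pancreas were higher. Of 26639 genes tested, 7535 were higher and 8257 were lower after irradiation at an adjusted p under 0.05 (limma, n = 3 pools per group). A change of at least 2-fold was seen for 3785 higher and 2487 lower genes, and the latter count was 1630 with normexp background correction, 1614 with normexp and quantile normalization, and 4271 with spike-in scaling. Among the 17782 genes with a RefSeq symbol, 5980 were higher and 5365 lower. Scaled to the spike-in control probes in place of the 75th percentile, 4806 genes were higher and 10799 lower, so that 30.8% of the called genes were higher in place of 47.7%, and the median of all genes was -0.34 in place of -0.06 on the log2 scale. The mean log2 spike-in level over the 75th percentile was 2.74, 3.11 and 2.85 on the unirradiated arrays. On the irradiated arrays it was 3.07, 3.31 and 3.17, so that the groups overlapped. The 3 irradiated arrays all lay on 1 side of the 3 unirradiated arrays for 67.4% of genes, where chance gives 10%.

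Genes that p53 activates after DNA damage rose together. Of 35 measured p53 target genes, 28 rose, 1 fell and 6 did not pass the threshold, with a median log2 change of 1.42 (camera adjusted p = 1.26e-10; adjusted p = 0.0605 with an estimated correlation). Cdkn1a, an inhibitor of cyclin-dependent kinases that stops the cell cycle, rose 24.4-fold, from -0.90 ± 0.12 to 3.71 ± 0.04 (SD, n = 3 pools each; log2 change 4.61 ± 0.09 SE, adjusted p = 2.62e-05). Its probe lies on chromosome 17 at 29237377 to 29237436 of mm9. Gdf15, a secreted stress cytokine, rose 13.7-fold (log2 change 3.77 ± 0.18 SE). Eda2r, a death-receptor family member, was not well above background on any unirradiated array and was at least 4.05-fold higher. Over the alternatives the log2 change of Eda2r was as small as 0.94. The exception was Btg2, which was lower by a log2 change of -0.82. In the list of BCL2 family members and caspases, which shares 4 measured genes with other lists, 10 of 25 genes rose, 7 fell and 8 did not pass, or 11 higher and 7 lower adjusted over the list alone. The list as a whole did not pass (camera adjusted p = 0.216; adjusted p = 0.471 with an estimated correlation), and with spike-in scaling 5 members were higher and 8 lower, at a median of -0.07 in place of 0.21. The pro-apoptotic genes Bbc3, Bok and Bax rose 3.89-, 2.96- and 2.67-fold. Birc2 and Cflar, which restrain apoptosis, rose as well, by log2 changes of 0.58 and 0.29, but did not pass with spike-in scaling. The members that fell were Bid, Bcl2, Bcl2l1, Birc3, Mcl1, Diablo and Casp8, which include genes that promote and genes that restrain apoptosis.

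Genes of DNA replication and mitosis fell without exception among those measured. All 31 replication genes were lower, with a median log2 change of -1.96 (camera adjusted p = 4.13e-08; adjusted p = 0.471 with an estimated correlation), and so were all 31 mitosis genes, the median gene being 6.05-fold lower (camera adjusted p = 3.76e-09; adjusted p = 0.471 with an estimated correlation). Mki67, the gene of the proliferation antigen Ki-67, went from 5.66 ± 0.80 to 2.35 ± 0.08 (SD, n = 3 pools each; log2 change -3.32 ± 0.37 SE, adjusted p = 0.000482). Ccna2, which encodes cyclin A2, was lower by a log2 change of -3.49, and the origin-licensing genes Orc1 and Cdc6 by -3.39 and -3.38. Of 29 genes of DNA damage response and repair, 24 fell, 1, Dclre1c, rose (log2 change 0.50, or 0.22 with spike-in scaling, where it did not pass) and 4 did not pass (median -0.75, camera adjusted p = 1.55e-06; adjusted p = 0.173 with an estimated correlation). Among them were Fancd2 (log2 change -2.71), Fanca (-2.34) and Brca1, which was not well above background on any irradiated array and at least 3.94-fold lower, all of which act in homologous recombination or crosslink repair. Over the alternatives the log2 change of Brca1 was as weak as -0.82. Within the unirradiated group, replicate 3 lay below the mean of replicates 1 and 2 by a log2 difference of -1.25 in the mitosis list and -1.13 in the replication list. With the pancreas list score as a covariate, all 3 lists passed, with medians of -1.39 for replication, -2.04 for mitosis and -0.69 for DNA damage, but single calls fell to 1, 5 and 11 lower members. Ccna2, Orc1, Cdc6 and Fancd2 then had log2 changes of -2.80, -2.47, -2.75 and -2.17, and these and Brca1 did not pass, at adjusted p between 0.0668 and 0.0846. The score lies far apart between the groups, which lowers the precision of this fit, so the lost calls cannot decide whether pancreatic RNA mattered.

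Erythroid genes had the largest decreases of any list. Of 30 measured members 27 fell, none rose and 3 did not pass (median log2 change -4.77, camera adjusted p = 8.8e-10; adjusted p = 0.471 with an estimated correlation). The 3 were Hemgn, Sptb and Epor, at log2 changes of 0.05, 0.33 and -1.08, and Epor passed as lower with spike-in scaling. The globin genes Hbb-b2 and Hba-a1 fell by log2 changes of only -2.15 and -0.73. Rhd, which encodes a red cell blood group antigen, stood at 2.41 ± 1.07 (SD, n = 3 pools) without irradiation and was not well above background on any irradiated array, at least 362-fold lower (limma adjusted p = 7.98e-05; probe on chromosome 4 at 134452018 to 134452077 of mm9). Add2, a subunit of the membrane-skeleton protein adducin, was at least 333-fold lower. Over the alternatives the log2 changes of Rhd and Add2 were as weak as -6.54 and -6.15, under these bounds. Kel, a further blood group antigen, fell 259-fold, from 3.70 ± 0.99 to -4.32 ± 0.12 (SD, n = 3 pools each). Slc4a1, the band 3 anion exchanger of the red cell membrane, fell 65.7-fold, and the membrane-skeleton gene Epb42 fell 103-fold. Tfrc, the transferrin receptor through which precursors take up iron, fell 30.4-fold. Of the megakaryocyte and platelet genes, 2 of 16 rose, none fell and 14 did not pass (median 0.25, or -0.04 with spike-in scaling; camera adjusted p = 0.0951; adjusted p = 0.745 with an estimated correlation). Those that rose were Clec1b, 2.01-fold, and Itga2b, at a log2 change of 0.47. Itga2b did not pass with spike-in or median scaling, with no filter on dim probes, with the pancreas list score as a covariate, with slide row 1 alone, or without unirradiated replicate 2 or any 1 irradiated array, at adjusted p between 0.0573 and 0.455. Adjusted over the list alone, 1 was higher and none lower. Without unirradiated replicate 1 or 2 the list passed as higher, at camera adjusted p = 0.031 or 0.0343, in a range from 0.031 to 0.45 over 20 alternatives at the preset correlation. Unirradiated replicate 3 lay below the mean of replicates 1 and 2 by -1.32 in the erythroid list and by -0.59 in the megakaryocyte list. The mean change of the erythroid list differed from that of the megakaryocyte list by -5.01 and from that of the neutrophil list by -4.29 on the log2 scale (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow, also after adjustment over the 9 pairs of lists compared).

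B cell and T cell genes fell, and markers of plasma cells rose. All 21 measured B cell genes were lower (median log2 change -2.63, camera adjusted p = 4.54e-11; adjusted p = 0.352 with an estimated correlation). Fcer2a, the low-affinity IgE receptor of mature B cells, fell 21.0-fold (log2 change -4.39 ± 0.15 SE), and Pax5, the transcription factor that maintains B cell identity, fell 9.55-fold. Of 24 T cell genes 22 fell, 1 rose and 1 did not pass (median -1.76, camera adjusted p = 1.2e-08; adjusted p = 0.471 with an estimated correlation). The CD8 chains Cd8b1 and Cd8a fell 15.7- and 6.82-fold, and Lef1, a transcription factor of naive T cells, 9.01-fold. Cd4 was the member that rose, by a log2 change of 0.31, and with spike-in scaling it stood at 0.03 and did not pass. Regulatory T cell genes went both ways, with 3 of 10 higher, 4 lower and 3 not past the threshold (median -0.14, camera adjusted p = 0.732; adjusted p = 0.898 with an estimated correlation). Itgae, Izumo1r, Ctla4 and Foxp3 fell, Itgae the furthest at 3.87-fold. Lrrc32 rose 1.71-fold, and Il2ra and Tnfrsf4 rose but did not pass with spike-in scaling. NK and cytotoxic lymphocyte genes also went both ways, with 7 of 16 higher, 3 lower and 6 not past it (median 0.28, camera adjusted p = 0.334; adjusted p = 0.832 with an estimated correlation), or 7 higher and 4 lower adjusted over the list alone. With spike-in scaling the median was -0.00, with 1 gene higher, Gzmb, and 5 lower. Gzmb, which encodes the cytotoxic protease granzyme B, rose 4.34-fold, and Klrd1, an NK cell receptor chain, fell 2.53-fold; Eomes and Tbx21, transcription factors of NK cells, were lower by log2 changes of -0.73 and -0.47. The mean change was -2.24 for the B cell minus the regulatory T cell list, -1.58 for the T cell minus the regulatory T cell list and -2.03 for the T cell minus the NK list on the log2 scale (two-sided exact permutation p = 0.1 for each, the smallest possible, so that this test could not pass 0.05).

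Among plasma cell genes 10 of 11 rose and 1, Irf4, fell (median log2 change 1.17, camera adjusted p = 0.00116; adjusted p = 0.471 with an estimated correlation). Jchain, the chain that joins secreted IgM and IgA, rose from 5.67 ± 0.26 to 7.09 ± 0.07 (SD, n = 3 pools each), a 2.69-fold change, and Derl3, of endoplasmic reticulum-associated degradation, rose 3.29-fold. Derl3, Xbp1, Creld2 and Fkbp11 are genes of the secretory pathway, which exocrine pancreas uses as well, and the pancreas list was higher on the same arrays by a median log2 change of 6.90. With the pancreas list score as a covariate the plasma cell list had a median of 1.08 and passed (camera adjusted p = 0.00307, in a range from 0.000403 to 0.00307 over 20 alternatives at the preset correlation). That fit cannot exclude a pancreatic source, because the score is a log2 value that lies far apart between the groups. Germinal centre B cell genes did not pass as a list, with 1 of 9 higher, 4 lower and 4 not past the threshold (median -0.22, camera adjusted p = 0.146; adjusted p = 0.471 with an estimated correlation). Rgs13 fell 11.2-fold, Lmo2 and Gcsam fell too, and S1pr2 rose but did not pass with spike-in scaling, where 6 members were lower and none higher. Of 11 genes of MHC class II presentation 10 fell and 1 rose (median -0.95, camera adjusted p = 0.000373; adjusted p = 0.471 with an estimated correlation). The class II transactivator Ciita fell 2.18-fold and the invariant chain Cd74 fell 1.64-fold, while the protease Ctss rose 1.89-fold. Dendritic cell genes were lower in 7 of 14, higher in 1 and not past the threshold in 6, with a median of -0.44 (camera adjusted p = 0.0302; adjusted p = 0.484 with an estimated correlation), or 1 higher and 6 lower adjusted over the list alone. The list did not pass with quantile normalization (camera adjusted p = 0.0522) or without unirradiated replicate 3 (0.0526), in a range from 0.00861 to 0.0843 over 20 alternatives at the preset correlation. Batf3 was the member that rose, and with spike-in scaling it did not pass. Cd209a fell 3.82-fold and Ccr9 3.62-fold, while Siglech and Tcf4 did not pass, at log2 changes of -0.15 and -0.13.

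**Figure D1:**
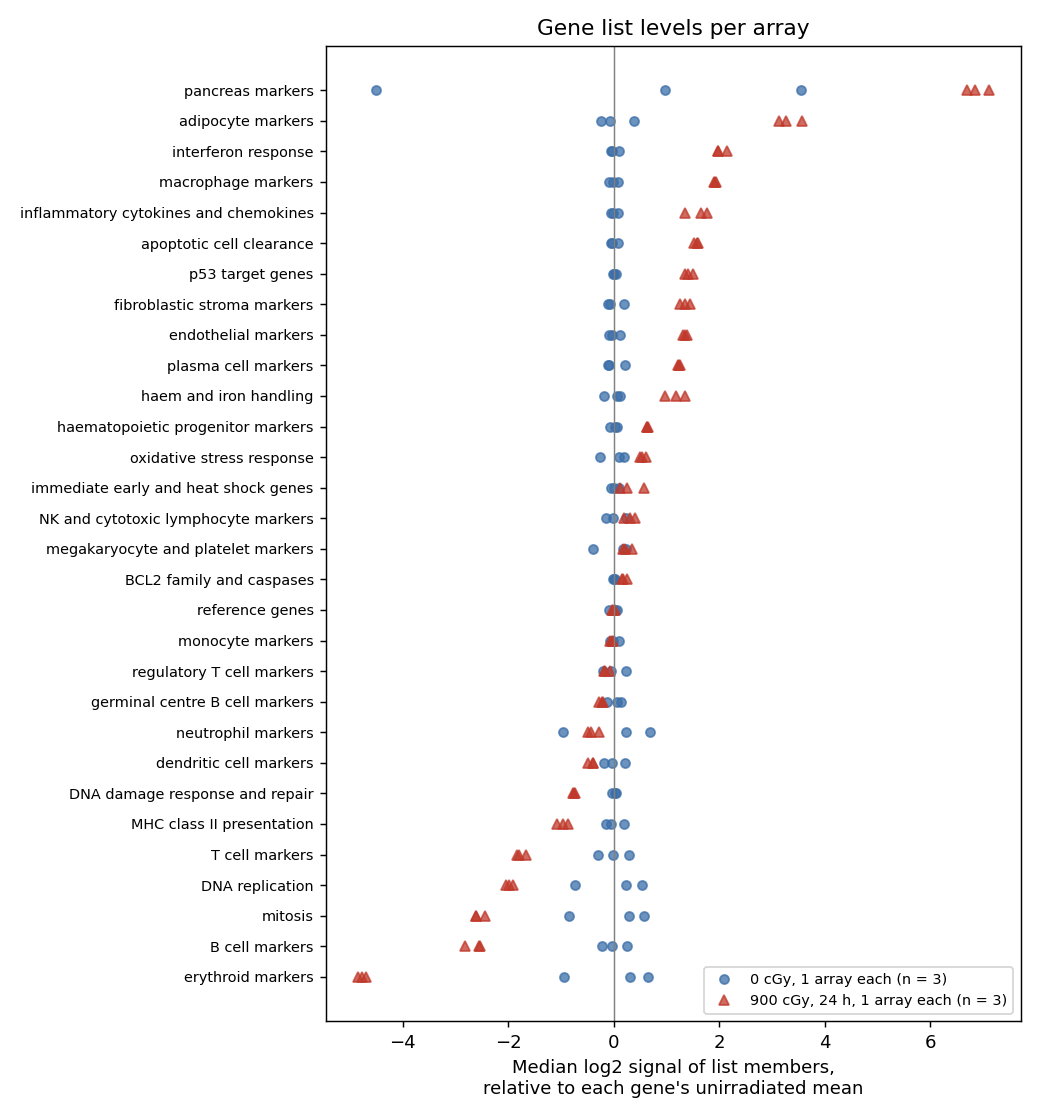
Each row is a gene list, and each point is 1 array; the horizontal axis gives the median log2 signal of the list's members relative to each gene's mean over the unirradiated arrays, with circles for 0 cGy and triangles for 900 cGy. The erythroid list lies lowest, at -4.77 on average over the irradiated arrays, and the pancreas list lies highest, with its 3 unirradiated arrays spread from -4.51 to 3.55.

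All 22 macrophage genes rose, 11 of which another list also holds, and with spike-in scaling 21 passed as higher (median log2 change 1.94, camera adjusted p = 7.44e-12; adjusted p = 0.279 with an estimated correlation). Fcgr1, the high-affinity IgG receptor, rose 6.88-fold. Cd5l, a protein secreted by tissue macrophages, rose 6.71-fold, from 4.66 ± 0.10 to 7.41 ± 0.03 (SD, n = 3 pools each), and Siglec1, the sialoadhesin of marginal metallophilic macrophages, rose 5.63-fold. Monocyte genes did not pass as a list, with 2 of 12 higher, 2 lower and 8 not past the threshold; their median was -0.04, while their mean was 0.13 and the test pointed upward (camera adjusted p = 0.732; adjusted p = 0.843 with an estimated correlation). Cd14 rose 4.42-fold and Csf1r 2.10-fold, while Ccr2 fell 1.67-fold and Plac8 1.39-fold. With spike-in scaling 2 members were higher and 4 lower. Ccr2, at a log2 change of -0.74, did not pass with the pancreas list score as a covariate (-0.59, adjusted p = 0.13) or with slide row 1 alone (-0.59, adjusted p = 0.0666). Of 20 genes of apoptotic cell clearance 19 rose and 1, Elmo1, fell (median 1.58, camera adjusted p = 5.06e-09; adjusted p = 0.279 with an estimated correlation), among them Gas6, a bridge between dying cells and phagocyte receptors, 4.88-fold, and the complement gene C1qb, 4.53-fold. Another list holds 8 of the 20 as well. Genes of haem and iron handling rose in 9 of 13 cases, fell in 1, Tfrc, and did not pass in 3 (median 1.18, camera adjusted p = 0.00564; adjusted p = 0.279 with an estimated correlation), and 6 of them stand in another list. Hmox1, the haem oxygenase, rose 4.34-fold and Slc11a1, a phagosomal metal transporter, 5.17-fold.

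Neutrophil genes were lower in 5 of 18, higher in 2 and not past the threshold in 11 (median -0.40, camera adjusted p = 0.527; adjusted p = 0.898 with an estimated correlation). Camera pointed downward and fry upward (fry adjusted p = 0.941). With spike-in scaling 9 members were lower and 2 higher. Elane and Prtn3, proteases of the azurophil granules made by early precursors, fell 4.32- and 4.15-fold, and so did Mpo, Ctsg and Camp by smaller amounts. Cxcr2, a chemokine receptor of mature neutrophils, rose 4.04-fold and Fpr1 3.39-fold. With the pancreas list score as a covariate the log2 changes of Elane and Prtn3 were -1.11 and -1.14 and did not pass (adjusted p = 0.377 and 0.346), nor did they pass with slide row 1 alone, at -1.96 and -1.98 (adjusted p = 0.121 and 0.107). With that covariate no member of the list was lower, and its median was 0.09. The list lay lower in unirradiated replicate 3 than in the mean of replicates 1 and 2, by a log2 difference of -1.22, and without replicate 3 it passed as lower (camera adjusted p = 0.033, in a range from 0.033 to 0.981 over 20 alternatives at the preset correlation). Progenitor genes divided as well, with 6 of 12 higher, 4 lower and 2 not past the threshold (median 0.60, camera adjusted p = 0.299; adjusted p = 0.471 with an estimated correlation). The transcription factors Myb and Tal1 fell by log2 changes of -2.68 and -1.88, Kit and Flt3 fell by -1.16 and -0.66, and Procr, which endothelial cells express as well, rose 2.92-fold. Tal1 did not pass with the pancreas list score as a covariate (log2 change -1.42, adjusted p = 0.247) or with slide row 1 alone (-1.85, adjusted p = 0.0979).

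Interferon-responsive genes rose in 25 of 26 cases, with a median log2 change of 2.05 (camera adjusted p = 3.7e-11; adjusted p = 0.279 with an estimated correlation). Ifi44 rose 11.1-fold, from 0.08 ± 0.12 to 3.55 ± 0.10 (SD, n = 3 pools each; log2 change 3.47 ± 0.10 SE, adjusted p = 4.51e-05), and Ifit3 and Ifit2 rose 9.90- and 6.23-fold. The member that fell was Rsad2, with a log2 change of -1.06. Of 23 inflammatory cytokines and chemokines 20 rose, 2 fell and 1 did not pass (the median gene 2.83-fold higher, or a median log2 change of 1.32 with dim genes set to their bounds; camera adjusted p = 7.14e-07; adjusted p = 0.279 with an estimated correlation). Saa3, an acute-phase protein, rose 61.3-fold, and the monocyte-attracting chemokines Ccl12 and Ccl7 rose 19.6- and 17.8-fold. Tnf and Osm were the members that fell, by log2 changes of -1.01 and -0.57. Of 19 oxidative stress genes 11 rose, 3 fell and 5 did not pass (median 0.53, camera adjusted p = 0.0247; adjusted p = 0.484 with an estimated correlation), or 11 higher and 4 lower adjusted over the list alone. With spike-in scaling 7 were higher and 5 lower. The list did not pass without unirradiated replicate 3 (camera adjusted p = 0.082, in a range from 0.00307 to 0.082 over 20 alternatives at the preset correlation). Nqo1, Gpx1 and Gclc were the members that fell. Gpx3, a secreted glutathione peroxidase, rose 6.62-fold and Sod3, the extracellular superoxide dismutase, 2.71-fold. Immediate early and heat shock genes did not pass as a list, with 6 of 13 higher, 5 lower and 2 not past the threshold (median 0.31, camera adjusted p = 0.415; adjusted p = 0.484 with an estimated correlation). Ier3, Jun and Atf3 rose 3.14-, 2.77- and 2.59-fold, and Ier2, Egr1, Dnajb1, Hsph1 and Fosb fell.

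**Figure D2:**
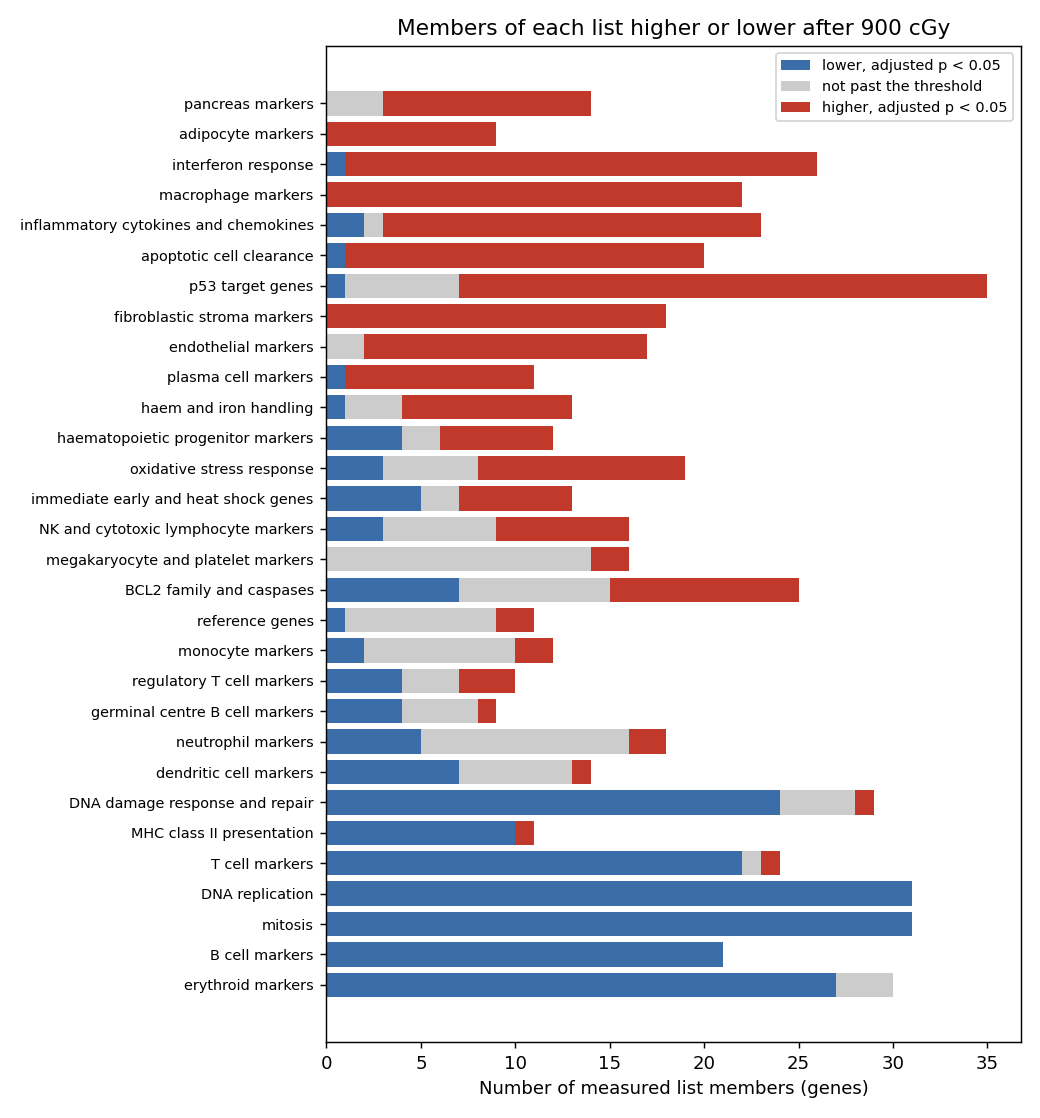
Bars count, for each gene list, the measured members that were lower, not past the threshold or higher after 900 cGy at limma adjusted p under 0.05; the horizontal axis is the number of genes and starts at 0. All 31 mitosis genes were lower, and all 22 macrophage genes were higher.

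Stromal and endothelial genes rose. All 18 fibroblastic stroma genes were higher (median log2 change 1.36, camera adjusted p = 5.06e-09; adjusted p = 0.279 with an estimated correlation), led by Pdpn, the podoplanin of T zone reticular cells, 7.21-fold, the matrix proteoglycan Lum, 5.80-fold, and Fap, 4.08-fold. Of 17 endothelial genes 15 rose, none fell and 2 did not pass (median 1.34, camera adjusted p = 3.14e-08; adjusted p = 0.279 with an estimated correlation). Robo4 and the VEGF receptor Flt1 rose 3.20- and 3.11-fold. Other probes of Flt1 gave log2 changes of 1.46 and 0.61. On the same arrays the adipocyte and pancreas lists were higher, by median log2 changes of 3.32 and 6.90. The reference genes had a median of -0.00 (mean -0.00, test direction upward, camera adjusted p = 0.983; adjusted p = 0.99 with an estimated correlation), with 2 of 11 higher, 1 lower and 8 not past the threshold. B2m rose 1.47-fold and Tbp fell 1.56-fold, and with spike-in scaling no member passed as higher while the list's median was -0.28. Tbp did not pass with slide row 1 alone (log2 change -0.62, adjusted p = 0.0566).

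Markers of neighbouring tissues rose with irradiation too. All 9 adipocyte genes were higher (median log2 change 3.32, camera adjusted p = 3.54e-06; adjusted p = 0.279 with an estimated correlation). Cidec, of the lipid droplet, rose 23.9-fold and the hormone gene Adipoq 16.5-fold. Cfd, or adipsin, rose by a log2 change of 3.81. Of 14 pancreas genes 11 rose and 3, Amy2a5, Ins1 and Ins2, did not pass (median 6.90, camera adjusted p = 0.00194; adjusted p = 0.481 with an estimated correlation). The largest increases among genes above background on every array included Pnliprp1, Cela3b, Cpb1, Cpa1, Dmbt1, Cela3a and Ctrc, between 105- and 153-fold, and of these all except Dmbt1 encode pancreatic digestive enzymes or their relatives. With 1 array left out their log2 changes ranged widely, from 4.65 to 9.11 for Cpa1, from 4.38 to 8.82 for Cela3a and from 5.46 to 8.76 for Pnliprp1, and with slide row 1 alone none of these 7 passed. Their levels differed between the unirradiated pools: Cpa1, pancreatic carboxypeptidase A1 (probe on chromosome 6 at 30595240 to 30595299 of mm9), stood at -4.59, 4.33 and 1.49 in unirradiated replicates 1, 2 and 3, and at 7.53, 7.76 and 7.38 in the irradiated ones (log2 change 7.15 ± 2.09 SE, adjusted p = 0.0247). With an intensity trend and robust variances Cpa1, Cela3b, Cela3a, Cela2a, Pnlip and Reg1 did not pass, at adjusted p between 0.0529 and 0.0859, and Cpa1 did not pass either when any 1 irradiated array was left out (0.0596, 0.0632 and 0.059). Over 20 alternatives the adjusted p of Cpa1 ranged from 0.00016 to 0.162. The probes of the pancreas list took 0.00106, 0.0785 and 0.0157% of the signal of the 3 unirradiated arrays and 0.728, 0.910 and 0.713% of that of the irradiated ones.

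**Figure D3:**
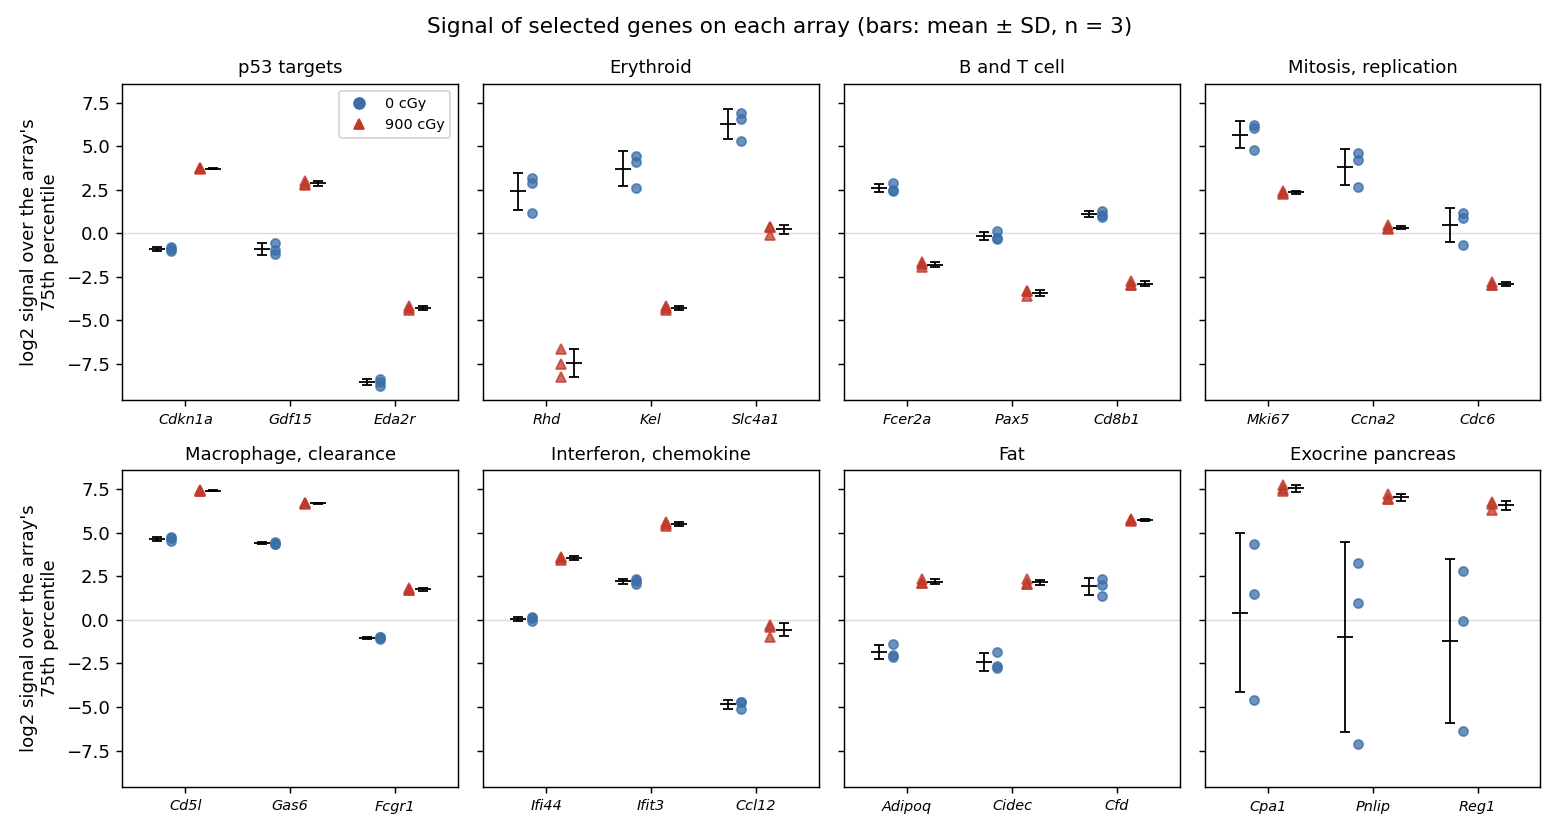
Each panel shows 3 genes of 1 group of lists on all 6 arrays, as log2 signal over the array's 75th percentile on the vertical axis, with circles for 0 cGy, triangles for 900 cGy, and bars for the mean ± SD of 3 pools. Cdkn1a lies at 3.71 on average after irradiation against -0.90 without it, Rhd lies at -7.46 after irradiation, and the circles of the exocrine pancreas genes are spread over several log2 units while the triangles lie together.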

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

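The tests weighed in this part were chosen after the patterns were seen, except for the counts over other splits of the arrays.

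Among 140 control probes, 8 of which served for the spike-in scaling, 2 others gave signal above the unirradiated level on all 3 irradiated arrays by a mean log2 difference of over 1. The probe ERCC-00079_170 was higher by 1.34, at -5.63 ± 0.17 without and -4.29 ± 0.37 with irradiation (SD, n = 3 arrays each), and ERCC-00138_246 was higher by 1.15, at -6.38 ± 0.20 and -5.23 ± 0.03. By the mirrored rule 2 other control probes were lower, ERCC-00156_158 by a log2 difference of -1.54 and ERCC-00168_248 by -1.29.

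Of the 10 ways to split the 6 arrays 3 against 3, only the real grouping, 1 split, reached its counts: 7535 genes higher, 8257 lower, 3785 at least 2-fold higher and 2487 at least 2-fold lower, while the highest count of any other split was 0 in limma for each of these, with at most 313 genes at an unadjusted p under 0.05. For the gene lists, 4 of the 10 splits gave as many lists past the threshold as the real grouping, which gave 20, and the highest of the others was 21. With 10 splits no share under 0.05 can be reached. Each of the other splits puts 2 irradiated arrays on 1 side.

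The exocrine pancreas genes were far higher after irradiation, and they also differed between unirradiated pools. Their mean over 12 members was -4.37, 3.32 and 0.93 in unirradiated replicates 1, 2 and 3, and 6.82, 7.17 and 6.78 in the irradiated ones. The spread of 7.69 between unirradiated pools argues against irradiation alone having switched these genes on. All 12 members shared 1 order of these pools. RNA of pancreatic tissue entering the pools in differing amounts, a candidate source, would give such an order. Any other source common to the 12 genes would give it too, so the shared order cannot decide between them. Ins1 and Ins2 were higher by 0.79 on average, under the bound of 2 set for islet genes that rose like the exocrine ones, but this rests on irradiated replicate 2, which also had the highest exocrine mean: the insulin genes averaged -3.33, -3.39 and -3.66 without irradiation and -3.28, -1.49 and -3.25 with it, a change of 0.19 without that replicate. Islet tissue in that pool stays open, and so does the reason why the irradiated pools held more exocrine RNA.

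Unirradiated replicate 3 had less signal of erythroid and dividing cells than replicates 1 and 2. Dilution by RNA of another tissue would lower every spleen list, yet the B cell list was higher there by 0.34. An irradiated pool under a wrong label is argued against by the p53 target list, which differed by -0.016. Less cell division, and a different share of erythroid and granulocyte precursors in that pool, may each remain, with the erythroid list at -1.32 and the neutrophil list at -1.22, and neither was tested.

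Macrophage, stroma and endothelial lists were higher after irradiation. A loss of B cells and erythroid cells would raise the share of every cell type that was not lost itself. The macrophage list rose by 1.67 more than the mean of the monocyte, megakaryocyte and NK lists. Whether the cells of those lists were lost too was not measured, so this difference cannot decide for or against such a loss as the source. The stroma and endothelial lists rose as well, by medians of 1.36 and 1.34. The scaling to the 75th percentile is argued against as the source, because the median of the macrophage list was 1.66 with spike-in scaling. More macrophages, a larger share of unchanged macrophages after the loss of other cells, and more transcripts per macrophage cannot be told apart. The median change of 1.94 is relative to the whole array and can hold each of them, and no cell number was measured here. With the pancreas list score as a covariate the stroma and endothelial list medians were 1.42 and 1.36 and both passed. This fit cannot decide whether pancreatic tissue was the whole source of that rise. The score is a log2 value. Pancreas probes took 0.00106 to 0.0785% of the signal of unirradiated arrays, against 0.713 to 0.910% of irradiated ones. Stroma RNA added in proportion to pancreatic RNA would hardly show at the low unirradiated shares. Fat, whose list was higher on the same arrays by a median of 3.32, was not tested, and both sources stay open.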

How the results depend on the processing

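The tests with the pancreas list score as a covariate and with slide row 1 alone were chosen after the results were seen. That score lies far apart between the groups, which lowers the precision of a fit with it. Calls lost with the score therefore cannot by themselves show a dependence on pancreatic RNA. Few arrays and low signal over background limit what dim genes can show, and a block for slide could not be run, since all arrays share 1 slide. Of the 107 named genes, 80 passed in the same direction under every alternative that tested them. The size of a change could still shrink. Over the alternatives the weakest log2 change was -1.89 for Rgs13, -0.87 for Itgae, -4.96 for Epb42 and -6.95 for Kel. It was 2.98 for Ccl12 and 3.14 for Ccl7. Where a cause is not stated, the cause was not tested.

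Genes at least 2-fold lower numbered 1630 with normexp background correction, 1614 with normexp and quantile normalization, 4271 with spike-in scaling and 3751 with every probe on its own, where more items were tested. Higher genes numbered 4806 with spike-in scaling. With the pancreas list score as a covariate 4475 were higher and 3374 lower, and with slide row 1 alone, which leaves 1 irradiated array whose spread is taken from the others, 4466 and 3931. The deposited value table gave 7519 higher and 8303 lower genes. Leaving out 1 array gave 6452 to 7766 higher, 6814 to 8917 lower, 3660 to 3971 at least 2-fold higher and 2303 to 2741 at least 2-fold lower genes.

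The replicate numbers did not pair the arrays. Each gene's group mean was subtracted, and the remaining deviations of arrays of 1 number were correlated across genes, which are not independent replicates. These correlations were 0.0732, 0.117 and -0.00214, while those of the signals themselves were 0.941, 0.950 and 0.960 for replicates 1, 2 and 3. With a replicate block 7145 genes were higher and 7560 lower.

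The dendritic cell list had an adjusted p of 0.0522 with quantile normalization, 0.0556 with normexp and quantile normalization, 0.0843 with slide row 1 alone, and 0.013 to 0.0526 with 1 array left out. With 1 array left out, the oxidative stress list ranged from 0.0121 to 0.082, the neutrophil list from 0.033 to 0.903 and the megakaryocyte list from 0.031 to 0.45. Without unirradiated replicate 3 the dendritic (0.0526) and oxidative (0.082) calls ended and the neutrophil list passed (0.033). The megakaryocyte list passed without unirradiated replicate 1 (0.031) or 2 (0.0343) and with slide row 1 alone (0.04). The germinal centre list passed with the covariate (0.0229). The pancreas list turned in direction with it (0.883), by construction, as did Cela3b (-0.51), Cpa1 (-1.05), Cela3a (-1.28), Cela2a (-0.15), Pnlip (-1.74) and Reg1 (-0.66).

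With an estimated correlation none of the 20 lists passed. The adjusted p was 0.0605 for p53 targets, 0.173 for DNA damage, 0.352 for B cells, 0.481 for pancreas, and 0.484 for dendritic cells and oxidative stress. It was 0.471 for DNA replication, mitosis, plasma cells, T cells, MHC class II and erythroid cells. It was 0.279 for macrophages, stroma, endothelium, interferon, inflammatory genes, clearance, haem and iron, and adipocytes. With fry the BCL2 family (0.000128), germinal centre (0.0035), monocyte (0.029), progenitor (0.000293) and immediate early (0.00189) lists passed as well.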

Other observations

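The comparisons between lists and the look at Xist and Ddx3y were chosen after the results were seen.

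Among the genes that were not well above background on any unirradiated array, the 3 with the largest bounds that the naming rule took were Reg3g, Tnfsf4 and Cldn3. Tnfsf4, the ligand of the T cell costimulator OX40, was at least 15.2-fold higher after irradiation (limma adjusted p = 6.09e-05, n = 3 pools per group), and Cldn3, a tight junction protein of epithelia, at least 8.69-fold higher. Over the alternatives the log2 changes of Tnfsf4 and Cldn3 were as small as 1.98 and 1.49. Reg3g, a secreted antibacterial lectin of epithelia, was at least 20.7-fold higher, with irradiated arrays that differed more (-1.94 ± 1.36 SD). Its log2 change was as small as 2.53 over the alternatives. The pancreas list was higher on the same arrays as Reg3g and Cldn3, by a median log2 change of 6.90. In the other direction, Slc25a21, a mitochondrial carrier, was at least 38.6-fold lower, with a log2 change as weak as -3.53 over the alternatives. Cldn13 fell 121-fold and Ctse, cathepsin E, fell 84.7-fold, beside the erythroid genes Ermap (82.3-fold) and Trim10 (59.9-fold), with unirradiated spreads of 0.76 to 1.22 (SD). Other probes of Ermap gave log2 changes of -6.52 and -0.53, and the latter did not pass with every probe tested on its own (limma adjusted p = 0.06).

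The change of the mitosis list minus that of the replication list was -0.62 on the log2 scale (two-sided exact permutation p = 0.1, the smallest possible, so that a difference could not pass 0.05). The same difference was -0.65 for the B cell minus the T cell list, -3.39 for the B cell minus the plasma cell list, and 1.76 for the macrophage minus the monocyte list, each at that exact permutation p.

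The adipocyte list, with 2.88, 3.09 and 2.98 on the irradiated arrays, differed much less between the unirradiated pools than the exocrine genes did, at -0.22, 0.28 and -0.06 in replicates 1, 2 and 3. The order of these pools was the same as for the exocrine genes, with replicate 1 lowest and replicate 2 highest. Irradiated replicate 2 was the highest irradiated array in both. Xist, transcribed from the inactive X chromosome, and the Y-linked Ddx3y were both measured on every array, and the sex of the mice in each pool is not given in the sources used here, so these values cannot be set down to irradiation. Xist stood at 0.58, 0.16 and 0.40 without irradiation and at -0.61, -0.49 and -0.00 with it, for replicates 1, 2 and 3 in turn (limma adjusted p = 0.0144). Ddx3y stood at 0.83 ± 0.40 and at 0.17 ± 0.76 (SD, n = 3 pools each; limma adjusted p = 0.2).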
